A study of Aspergillus nidulans with 2 samples.

How the data were processed

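Expression was measured with 2-colour cDNA microarrays in 2 samples, each an array on which RNA of menadione-exposed and of untreated mycelia was hybridised together. Per the labels' protocols, strain FGSC 26 was grown in 500 ml flasks with 100 ml of minimal-nitrate medium of pH 6.5 with 0.5% yeast extract, and RNA came from about 100 mg of dried mycelium. Both samples form 1 group, menadione against untreated, with the dyes exchanged between the flip and the flop array.

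Per the labels' protocols and the series' design text, the authors scanned the arrays with a GenePix 4000B scanner, took intensity ratios with GenePix Pro 3.0, and normalized the ratios with a LOESS procedure block by block in SAS for Windows version 8. Clones were printed in duplicate. Each deposited column is titled a summary of normalized data, so spots, and possibly several hybridisations, were combined before deposit by a rule not given in the sources used here. Background correction and the rule that left cells empty are not given in the sources used here either. The scanner files were not used here.

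The values, deposited as a series matrix, were taken as log2 ratios: they take both signs, many lie between -1 and 1, and their medians are 0.01 (flip) and 0.10 (flop). The base of the logarithm is not stated. The value farthest from 0 is -5.94, which as a log10 ratio would exceed in size the 4.82 that a 16-bit scanner can give. A natural logarithm stays possible, in which case a value of 1 is a 2.72-fold difference. The values were tested as deposited, without further scaling or centring. The SD of all values was 0.965 on the flip array and 1.16 on the flop array. The direction of the ratio is not stated: red over green on both arrays would make the treatment run in opposite directions in the 2 columns, and the columns correlated at 0.844 over shared probes. Both were read as menadione over untreated, the first channel over the second. The correlation does not settle this, since a dye effect in 2 columns of red over green could also give it.

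Intensities were not used here, so depth or signal over background behind each ratio is unknown. The flip array had 484 empty cells and the flop array 1266, 482 probes were empty on both, 784 had a value on the flip array alone and 2 on the flop array alone. Only the 2265 probes with both values were tested.

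Log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom per probe, the test leaned on a prior variance of 0.0538 with 1.95 prior degrees of freedom. If both columns run as menadione over untreated, a dye effect of a probe cancels in the mean of both arrays and adds to its spread. If the 2 arrays carried the same 2 RNA extracts they are 1 biological replicate, and the p-values say nothing of the spread between cultures. A count by size is therefore given beside the test: probes at least 2-fold in the same direction on both arrays. Errors are SDs over the 2 arrays.

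The procedure was tested on simulated data for the menadione comparison, with 2265 probes, 2 arrays, the fitted variances, and 200 probes changed. Of the probes changed 4-fold, 68.2% were called. Of those changed 1.5-fold or 2-fold, 0% were called at 0.05 adjusted p. Of 2065 unchanged probes, 2 were called, and 0 of the changed probes were called with the wrong sign. The adjusted cut-off depends on how many probes are changed. In the data 557 probes passed, with means down to 0.745 in size, which is below 2-fold. The simulated rates therefore do not carry over to the data.

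Gene names came from the platform annotation, which is old, updated by Entrez gene ID through the RefSeq table of assembly ASM1142v1 of strain FGSC A4. It names 1 gene for each of 2779 probes (2064 genes), none of them several, and leaves 754 probes unnamed here. All 2779 gene IDs matched RefSeq and 0 symbols changed. Most genes carry only a locus tag: of the 1455 genes tested, 213 had a symbol. No coordinates are given, since the genome build behind the clones is not given in the sources used here. For gene values, the log2 ratios of a gene's probes were averaged per array before the fit, and 285 genes had more than 1 probe.

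The named genes were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest genes with a symbol among those past an adjusted p of 0.05 with the same sign on both arrays, and up to 4 measured members of each list with the largest absolute mean. Genes with only a locus tag were passed over: 80 with a larger mean than the last of the 12 highest and 62 below the last of the 12 lowest. The 20 gene lists were fixed by theme before the data were examined, by symbols, 15 of which are on the array, and by words in product descriptions. No description was in the tables used, so the other members among the 102 listed symbols were assigned to the same themes from their symbols after the values had been seen, and 4 further lists (closing section) were made then. Lists with at least 5 measured genes were tested with camera (preset correlation of 0.01, and an estimated one) and fry, over 5 lists.

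Alternatives tried were centring each array, scaling to a common spread, robust moderation, an unmoderated one-sample statistic, other thresholds, gene averages, probes with 1 value, probes at the extremes left out, each array alone, the flop array's sign turned, which was planned for the correlation of the arrays and chosen after the data were seen for the counts and named genes, and natural logarithms, also chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the tests of probe pairs and for plots, with 1000 bootstrap resamples and 100000 permutations. Resampling was over genes for probe pairs and over adjacent pairs for neighbouring genes. Camera's alternative with robust moderation was run on the moderated statistics (cameraPR).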

Results

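Transcript levels of the filamentous fungus Aspergillus nidulans (Emericella nidulans) were compared between mycelia exposed to menadione and untreated mycelia. Menadione is a quinone that cycles between its oxidised and reduced forms in the cell and produces superoxide. Strain FGSC 26 was grown for 18 h at 37 °C, moved to fresh minimal medium with or without 0.8 mM menadione (as its sodium bisulfite compound), and harvested after 6 h. The RNA of both cultures was hybridised together to 2-colour cDNA arrays made from 3533 expressed sequence tags. The 2 arrays carried opposite dyes: menadione RNA was labelled with Cy5 on the first array (flip) and with Cy3 on the second (flop). The flip array held a ratio for 3049 probes and the flop array for 2267 probes, and 2265 probes had a ratio on both. The number of arrays, 2, limits the precision of every value. The labels do not say whether the arrays carried RNA of separate cultures, so each p-value measures only the spread between 2 arrays, which may be technical.

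The series matrix does not state the direction of its ratios. Menadione RNA was the first channel of both samples, so a positive value is read here as higher with menadione. The 2 columns correlated positively and were taken to run the same way. The correlation does not show which way, and a shared dye effect could also give it. The direction of menadione over untreated is an assumption and is not stated. The opposite one would exchange higher and lower throughout, and red over green in both columns is not excluded by the labels. Values are read as log2, which is also not stated.

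Which transcripts differed after exposure to menadione was the question of the study. The largest increases among genes with a symbol that passed the test were those of treA (trehalase) and acuF (phosphoenolpyruvate carboxykinase), 9.13-fold and 7.01-fold higher with menadione. Another acuF probe, measured on the flip array alone, was at -1.02, in the opposite direction. The largest decreases among them were those of mirB, a siderophore transporter gene, and rpp1, 22.7-fold and 11.4-fold lower. By limma with Benjamini-Hochberg adjustment, 557 of 2265 probes (24.6%) passed an adjusted p of 0.05, of which 276 were higher and 281 lower with menadione. A ratio of at least 2-fold in the same direction on both arrays was measured for 412 probes, 200 higher and 212 lower. If the arrays were independent, 38.0 higher and 39.3 lower probes would be expected. A further 4 probes were at least 2-fold in opposite directions. Across probes, which are not independent replicates, the arrays correlated with a Pearson r of 0.844 and a Spearman rho of 0.849. The same sign was measured for 82.2% of probes, against 49.1% expected if the arrays were independent. The direction of the ratios was read in part from this agreement, so the agreement is no evidence for it. If both arrays carried the same RNA extracts, the agreement shows repeated measurement and not a repeated response. The median SD between the 2 arrays was 0.198 on the log2 scale. An adjusted p of 0.01 was passed by 0 probes in the same limma fit, in which 1035 probes had an unadjusted p under 0.05. Without moderation of the variances 0 probes passed 0.05 (390 at an unadjusted p under 0.05), 885 passed by limma after both arrays were scaled to a common spread, and 0 passed by limma (2 unadjusted) with the flop array's sign turned. The order and direction of the named genes hold only in the direction assumed. With the flop array's sign turned, treA was at -0.53, acuF at 0.10, mirB at 1.08 and rpp1 at 0.74. No mean log2 ratio smaller in size than 0.745 passed.

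**Figure D1:**
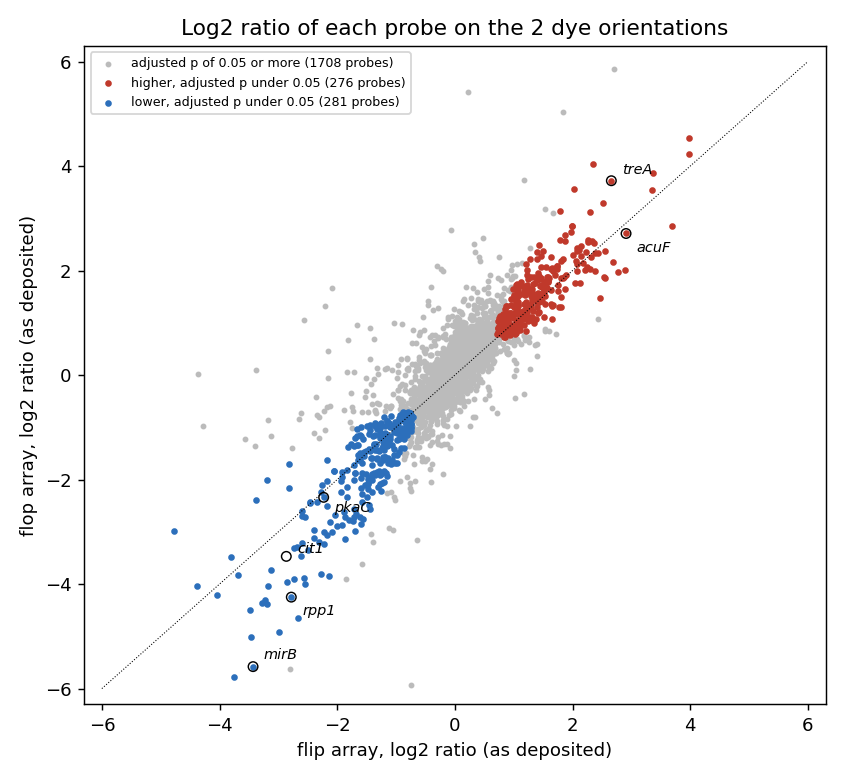
Log2 ratio of each of 2265 probes on the flip array (x axis) and the flop array (y axis), with 276 probes in red and 281 in blue past an adjusted p of 0.05 by limma. Open circles mark the gene means of 6 named genes (cit1 is the mean of 2 probes), and the dotted line marks equal ratios.

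Probes were assigned to genes by the platform annotation, and probes assigned to the same gene often differed. Over 388 pairs of probes from 285 genes, the Pearson r of the 2-array means was 0.111 (95% bootstrap interval over genes from -0.0140 to 0.229; one-sided permutation p = 0.0143). Over these pairs, the median absolute difference between the 2-array means of probes of 1 gene was 0.80. Between the single values of 1 probe on the 2 arrays, over all probes with both values, it was 0.28. These are unlike measures on unlike sets of probes. In 20 pairs both probes passed an adjusted p of 0.05 by limma, and 10 of these pairs changed in the same direction. A gene value is therefore that of the probes assigned to the gene, and of the 24 genes described next, the 12 highest and 12 lowest that have a symbol and passed, 3 had more than 1 probe measured on both arrays.

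**Figure D2:**
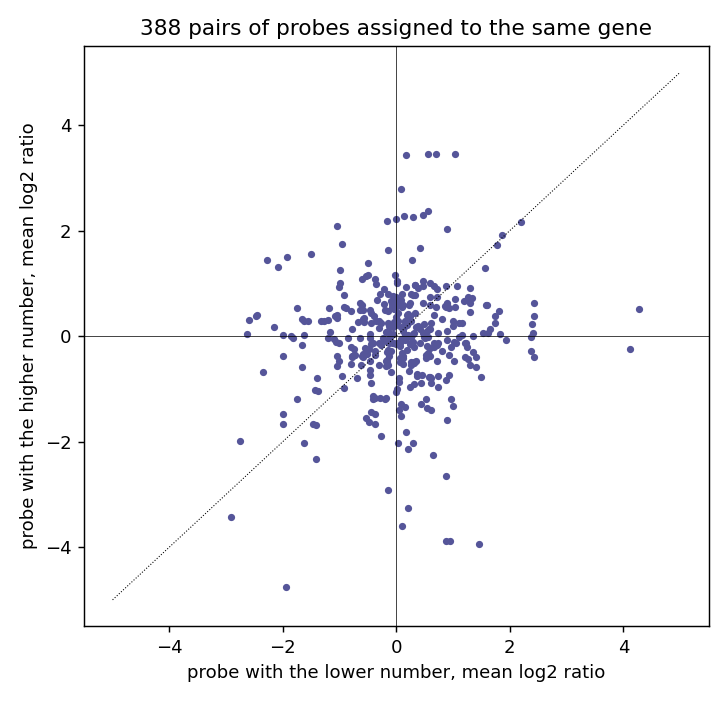
Mean log2 ratio over both arrays for 388 pairs of probes assigned to the same gene, with the lower-numbered probe on the x axis and the higher-numbered on the y axis. The points do not follow the dotted line of equality (Pearson r = 0.111).

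With probes of 1 gene averaged, 277 of 1455 genes passed an adjusted p of 0.05 by limma, 139 higher and 138 lower. Of the 213 genes with a symbol, 22 were higher and 27 lower. The highest of those that passed was treA, an acid trehalase, at a mean log2 ratio of 3.19 ± 0.75 (SD, n = 2). It was followed by acuF, phosphoenolpyruvate carboxykinase, at 2.81 ± 0.14, and hel10 at 2.18 ± 0.34. The 2 probes of hel10 were at 2.21 and 2.16. The gluconeogenic fructose-1,6-bisphosphatase gene fbp1 rose by 1.85 ± 0.28 and the cytochrome c oxidase subunit gene cox5b by 1.65 ± 0.21. The kinase gene imeB was higher by 1.62 ± 0.10, the glycolytic gpdA (glyceraldehyde-3-phosphate dehydrogenase) by 1.54 ± 0.33, and lcp5, a ribosome biogenesis factor, by 1.45 ± 0.14. The last of the 12 highest were EifCb (1.40 ± 0.25), ccg9 (1.24 ± 0.04), nde1 (1.23 ± 0.03) and the phosphodiesterase gene pdeB (1.11 ± 0.06). The 2 probes of ccg9 were at 2.41 and 0.07, so its increase rested on 1 of them.

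The lowest gene with a symbol that passed was mirB, a siderophore transporter, at -4.51 ± 1.52 (SD, n = 2). It was followed by rpp1 at -3.52 ± 1.04 and the citrate synthase gene cit1 at -3.17 ± 0.43, whose 2 probes were at -2.91 and -3.43. The DNA helicase gene chl1 fell by 2.45 ± 0.62, and the protein kinase A gene pkaC by 2.29 ± 0.08. The gene esdC, which acts in early sexual development, was at -2.25 ± 0.03. The chromatin protein gene nhp6 was at -1.78 ± 0.13, and hemA, which encodes 5-aminolevulinate synthase of heme synthesis, at -1.62 ± 0.01. The remaining of the 12 lowest were car2 (ornithine aminotransferase) at -1.55 ± 0.32, rad18 at -1.53 ± 0.25, steA, a regulator of sexual development, at -1.48 ± 0.04, and the heat shock gene awh11 at -1.38 ± 0.31. All 24 named genes passed by limma with adjusted p-values between 0.0423 and 0.0486. Of them, 5 had another probe measured on the flip array alone: acuF at -1.02, lcp5 at 0.26, pkaC at -0.52, rad18 at -0.04 and steA at 0.15. None of these 5 was 2-fold in the direction of the gene's other probe, and that of acuF was 2-fold in the opposite direction.

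The gene lists were themes fixed before the data were examined, but most members were assigned to them from their symbols afterwards. Members could be found only by symbol, which 213 of the 1455 tested genes had. Every count of a list therefore covers genes with a symbol alone, and genes of the same theme with only a locus tag are not counted. Counts adjusted over the list alone are therefore not independent evidence. Among glycolysis and gluconeogenesis genes, 3 of 3 measured members rose: acuF, fbp1 and gpdA. The other acuF probe, with a value on the flip array alone, was at -1.02. Of 3 measured genes of the TCA and related cycles, cit1 and the gene mean of mcsA (methylcitrate synthase) fell and acoA (aconitase) was at 0.41 ± 0.04, which did not pass. The value of mcsA, -0.88 ± 0.07, averaged 2 probes that passed in opposite directions in the fit of single probes, at -2.65 (limma adjusted p = 0.0351) and 0.88 (adjusted p = 0.0499). Both measured members of the respiratory chain list, cox5b and nde1, rose. The gene nde1 was placed there from its symbol alone, so its part in the respiratory chain is not established. Of the pentose phosphate pathway, the only measured gene with a symbol, the transketolase gene tktA, rose by 0.82 ± 0.06 (limma adjusted p = 0.0485, and 0.0513 with robust moderation). Adjusted over the list alone, 3 of 3 glycolytic and gluconeogenic genes passed. So did 3 of 3 genes of the TCA and related cycles (acoA higher) and 2 of 2 members of the respiratory list. These lists held fewer than 5 measured genes and were not given a set test.

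**Figure D3:**
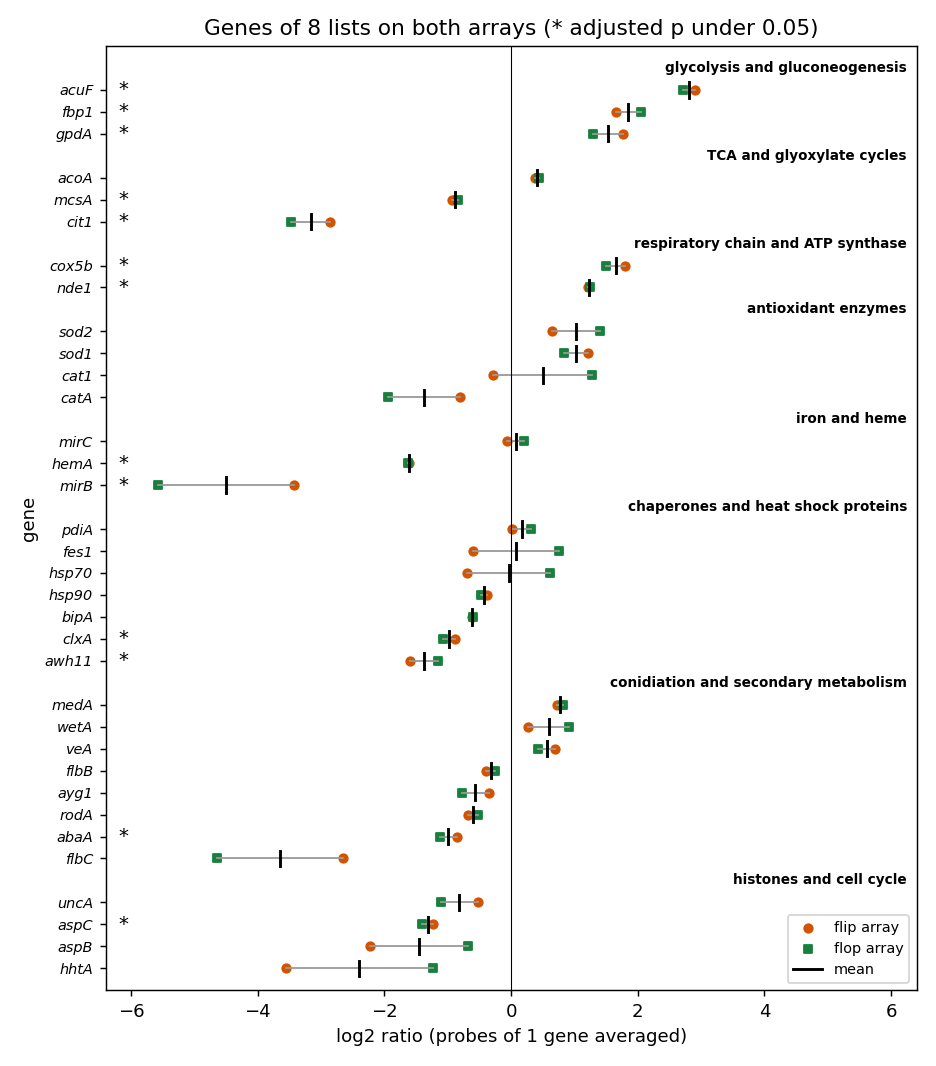
Log2 ratios (x axis) of the measured genes (y axis) of 8 lists, with the flip array as circles, the flop array as squares, their mean as a vertical black bar, and a star where the limma adjusted p was under 0.05. The 3 glycolytic and gluconeogenic genes lie above 0 on both arrays, whereas cat1, fes1, hsp70 and mirC differ in sign between arrays.

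On the array, 7 antioxidant enzyme genes had a symbol, of which 4 had values on both arrays. In the fit of gene means 0 passed by limma (3 at an unadjusted p under 0.05). In the fit of single probes, which gave the count of 557, the sod1 probe passed (adjusted p = 0.0453). The superoxide dismutase genes were at 1.03 ± 0.26 (sod1, adjusted p = 0.0519) and 1.03 ± 0.54 (sod2, adjusted p = 0.0913), and both had positive ratios on both arrays. The catalase gene catA was at -1.38 ± 0.81 (adjusted p = 0.0976), with other probes at 0.13 and -0.42 on the flip array alone, and the catalase gene cat1 at 0.50 ± 1.10, with opposite signs on the arrays. Adjusted over the list alone, 1 of the 4 passed (sod1). When the arrays were scaled to a common spread, catA fell and sod1 and sod2 rose past the threshold over all genes (adjusted p = 0.0165, 0.0263 and 0.0168 by limma).

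Of 3 measured iron and heme genes, 2 fell by limma, mirB and hemA, whereas the siderophore transporter gene mirC was at 0.07 ± 0.20. The same 2 passed when adjusted over the list alone. Of 7 measured chaperone genes, 2 fell: awh11, and clxA (calnexin) at -0.98 ± 0.13, which had another probe at -0.27 on the flip array alone. The ER chaperone gene bipA was at -0.61 ± 0.0047 and hsp90 at -0.43 ± 0.06, and neither passed over all genes. Of the bipA probes, which lay between -1.18 and -0.29, 1 passed in the fit of single probes (adjusted p = 0.0391). hsp70 was at -0.04 ± 0.93 (probes at -0.36 and 0.29, and another at -5.07 on the flip array alone), pdiA at 0.17 ± 0.21 and fes1 at 0.08 ± 0.97. Adjusted over the list alone, 3 chaperone genes passed, all lower.

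Among 8 measured genes of conidiation and secondary metabolism, 1 fell, the conidiation regulator abaA at -0.995 ± 0.19 (limma adjusted p = 0.0481, and 0.0504 with robust moderation). The regulator flbC was at -3.65 ± 1.40 (adjusted p = 0.0552) and medA at 0.78 ± 0.06 (adjusted p = 0.0507), neither past the threshold in the fit of gene means. Their probes passed in the fit of single probes (adjusted p = 0.0440 and 0.0474 by limma). Another medA probe, on the flip array alone, was at -1.73. Adjusted over the list alone, 4 passed, 1 higher and 3 lower. Of 15 measured cell wall genes, 2 fell: the chitinase gene chiA1 at -1.01 ± 0.13 and the chitin synthase gene chsE at -0.79 ± 0.04, the latter with an adjusted p of 0.0526 under robust moderation. The other 13 did not pass, among them chsF at -0.85 ± 1.85 and eng2 at -0.62 ± 0.24, and adjusted over the list alone 0 passed by limma (5 at an unadjusted p under 0.05). In the fit of single probes, 1 of 2 exgO probes was higher (1.24, limma adjusted p = 0.0391) and 1 of 2 chsA probes lower (-1.01, adjusted p = 0.0471). Of 4 measured histone, septin and kinesin genes, 1 fell, the septin gene aspC at -1.32 ± 0.11, with another probe at 0.69 on the flip array alone. The histone H3 gene hhtA was at -2.40 ± 1.65, the septin gene aspB at -1.46 ± 1.10 and the kinesin gene uncA at -0.82 ± 0.41, and the list alone also gave 1.

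Of 6 measured lipid and sterol genes, 1 fell, hmg1 (HMG-CoA reductase) at -1.21 ± 0.01. Not past the threshold were faa4 at -0.59 ± 0.10, pld2 at -0.48 ± 0.06 and idi1 at 0.46 ± 0.01. The 2 probes of faa4 were at -1.07 and -0.105, with another at -0.02 on the flip array alone. Of 6 measured proteasome and ubiquitin genes, 1 rose, skpA at 0.96 ± 0.08, with tom1 at 0.32 ± 0.16, rpt1 at 0.23 ± 0.28 and rpt3 at -0.22 ± 0.01. The 2 probes of tom1 were at 0.99, which passed in the fit of single probes (limma adjusted p = 0.0454), and -0.36. In both lists 1 gene passed when adjusted over the list alone. Of 2 measured sulfur metabolism genes, met2 fell (-0.96 ± 0.11) and sC was at 0.60 ± 0.16, and both passed over the list alone. The measured nitrogen assimilation genes, niiA (nitrite reductase) at -0.56 ± 0.14 and glnA (glutamine synthetase) at -0.22 ± 0.23 with another probe at 2.37 on the flip array alone, passed neither threshold. The ribosomal protein genes rps0 at 0.28 ± 0.05 and rps1 at -0.09 ± 0.05 and the drug transporter gene mdr1 at -0.15 ± 0.26 (probes at 0.46 and -0.75) did not pass either. The actin gene act1, often used as a reference, fell by 1.08 ± 0.02, but its 2 probes were at -0.27 and -1.90. The only measured translation factor gene with a symbol, EifCb, is among the genes named above. For the cytochrome P450 list and the quinone and flavin oxidoreductase list, 0 genes with a symbol had values on both arrays.

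The 5 fixed lists with at least 5 measured genes did not pass the camera test of a shift against the other genes. Their medians were -0.43 for chaperones, -0.44 for conidiation, -0.21 for lipid and sterol genes, -0.06 for the cell wall and 0.19 for the proteasome and ubiquitin. The 2-sided camera test with a preset correlation of 0.01 gave adjusted p-values from 0.405 (chaperones) to 0.510 (cell wall), and 0.610 for each list with an estimated correlation. With 2 arrays, an estimated correlation leaves that test 1 degree of freedom, so it could hardly pass and decides nothing. The fry tests set a list against no change, not against other genes. For movement in 1 direction the adjusted p-values were 0.136 to 0.324, and for change in either direction 0.0212 to 0.0418.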

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

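Turning the sign of the flop array for the counts and the named genes and reading the values as natural logarithms were chosen only after the data were seen, and the other alternatives were planned. With 557 probes past the threshold as reported, scaling both arrays to the same spread gave 885 and an adjusted p under 0.10 gave 951. Averaging probes of 1 gene, which also left out probes without a name, gave 277 genes, and keeping probes with a value on at least 1 array gave 305. An adjusted p under 0.01 gave 0 by limma, with 1035 probes at an unadjusted p under 0.05. The unmoderated one-sample statistic gave 0, with 390 probes at an unadjusted p under 0.05 and a smallest adjusted p of 0.284; it left out 28 probes with identical values on both arrays. Centring (683 probes), robust moderation (537), a further fold limit of 1.5 (557) or 2 (431), leaving out 2 extreme probes (561) and natural logarithms (557) stayed within 1.5 times, and all 557 probes remained called after centring. No test is possible on 1 array, so the count past the threshold has no value without either one. The 412 probes at least 2-fold on both arrays became 785 at 1.5-fold, 157 at 3-fold and 663 if the values are natural logarithms, and 671 to 708 on 1 array alone. With the flop array's sign turned, the correlation became -0.844, 4 probes were at least 2-fold on both arrays, and limma called 0 (2 at an unadjusted p under 0.05). Of the 12 highest and 12 lowest named genes 0 then passed by limma (over all genes 0, with 1 at an unadjusted p under 0.05), 10 kept their sign and 14 changed it: treA (-0.53), fbp1 (-0.20), imeB (-0.07), lcp5 (-0.10), EifCb (-0.18), ccg9 (-0.025), nde1 (-0.02), mirB (1.08), rpp1 (0.74), cit1 (0.30), chl1 (0.44), pkaC (0.055), nhp6 (0.09) and hemA (0.01). The 10 that kept it were also much smaller in size: acuF (0.10), hel10 (0.24), cox5b (0.15), gpdA (0.235), pdeB (0.04), esdC (-0.02), car2 (-0.225), rad18 (-0.18), steA (-0.03) and awh11 (-0.22). Without 1 array, the list medians ranged from -0.15 to -0.05 for the cell wall, from -0.62 to -0.47 for chaperones, from -0.39 to -0.37 for conidiation, from -0.33 to -0.09 for lipid and sterol genes and from 0.12 to 0.32 for the proteasome and ubiquitin (as reported, -0.06, -0.43, -0.44, -0.21 and 0.19). The 5 fixed lists stayed past no threshold under centring, scaling, robust moderation, single probes, an estimated correlation or the test of 1 direction by fry, with adjusted p-values from 0.136 to 0.610. The camera test with an estimated correlation, on 1 degree of freedom, could hardly have passed. Of 76 named genes, 0 changed direction under centring or scaling. Robust moderation leaves the means as they are, so it could change no direction. None that had passed changed sign on either array alone, but this was fixed in advance. Passing with 2 values of opposite sign was hardly possible, and the rule for the 12 highest and 12 lowest required the same sign. Scaling to a common spread brought 17 past the threshold, among them catA, sod1 and sod2, centring brought 3 (sod1, flbC and medA, whose probes also passed in the fit of single probes), and robust moderation lost 3 (chsE, abaA and tktA). The causes were not tested. Each ratio pairs both conditions on 1 array, so the test against 0 is already paired. Intensities were not used here, so how far weak signal limits a ratio is unknown.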

Other observations

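The tests of measurement error, of a constant offset and of a dye effect, and the lists of stress signalling, peroxisome, mitochondrial import and ribosome biogenesis genes, were chosen only after the data were seen, whereas the tests of empty cells and of neighbouring genes were set before their results.

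The genes with the 2 largest increases that passed the threshold carried only a locus tag and were chosen here after their values were seen. ANIA_02846 was at 4.26 ± 0.40 (SD, n = 2) and ANIA_04905 at 3.61 ± 0.35, 19.2-fold and 12.2-fold higher with menadione, each from 1 probe. The 2 lowest past the threshold without a symbol were ANIA_08483 at -4.24 ± 1.10 and ANIA_08953 at -4.13 ± 0.12. The rank and direction of these genes hold only in the direction of the ratio assumed here, which is not stated. With the flop array's sign turned, 0 genes passed by limma, these included (over all genes, 1 at an unadjusted p under 0.05). In lists made after the data were seen, also by symbol alone, 5 genes of stress signalling had values on both arrays. The stress MAP kinase gene sakA rose by 1.00 ± 0.13 (limma adjusted p = 0.0454), while pbs2 (its upstream kinase) was at 1.76 ± 0.97, the transcription factor gene atfA at 0.64 ± 0.04, the histidine kinase gene tcsC at 0.55 ± 0.12 and sho1 at 0.22 ± 0.45. Adjusted over the list alone 4 of the 5 passed, all higher, and as a set camera gave an adjusted p of 0.184 over 7 lists. With an estimated correlation, where camera has 1 degree of freedom and could hardly pass, the adjusted p was 0.712. Of 8 ribosome biogenesis genes, lcp5 rose and nop58 fell (-1.23 ± 0.26), and the set gave a camera adjusted p of 0.782. Of 3 peroxisome genes (pex7 at 0.79 ± 0.18, pex8 at -0.52 ± 0.26, pex26 at -0.44 ± 0.47) and 3 mitochondrial import genes (sam50 at 0.64 ± 0.03, tim13 at 0.19 ± 0.09, tim21 at -0.01 ± 0.25 with probes at -0.60 and 0.59), 0 passed by limma over all genes (1 of each at an unadjusted p under 0.05), and 1 of each list (pex7 and sam50, both higher) passed over the list alone.

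Probes of the same gene agreed far less than the same probe on the 2 arrays. Measurement error between the arrays is argued against: the 2-array mean has a reliability of 0.915, and the correlation over pairs of probes of 1 gene was 0.111 with an upper bound of 0.229. A constant offset of up to 300 probe numbers in either direction between probe numbers and gene names is argued against only weakly. The best of these 600 shifts reached 0.176, short of a bar that was set after the data were seen. It exceeded the 0.111 of the names as given, so the shifts do not favour the unshifted names. Larger offsets were not tested. A mismatch of another shape, such as clones that are not the gene they are annotated as, may account for it and stays open: empty cells of the flop array had a phi of 0.0374 between probes of 1 gene against a mean of 0.00197 after shuffling within stretches of 200 probe numbers (one-sided permutation p = 0.144), and cross-hybridisation was not tested. The correlation exceeded that of most shuffled names (one-sided permutation p = 0.0143), but its bootstrap interval reached below 0 and of 20 pairs in which both probes passed 10 had the same direction, so how much the names hold stays open.

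The positive correlation of the 2 columns could also come from a dye effect, if both columns held red over green and the treatment lay in the difference between them. That difference correlated at 0.0180 between probes of 1 gene (95% bootstrap interval from -0.0824 to 0.105), against 0.111 for the mean (one-sided permutation p = 0.0143, interval from -0.0140 to 0.229). With the gene names in doubt, low values are to be had under either reading, so this test decides nothing and a dye effect and a response to menadione cannot be told apart by it. What keeps the former open is that the labels give no direction of the ratio. The latter was assumed from the channel order, which does not settle it.

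Whether neighbouring genes moved together stays open. Over 236 pairs of adjacent measured genes the Pearson r was -0.0165 (95% bootstrap interval over pairs from -0.123 to 0.0909, 2-sided permutation p = 0.801). Pairs can share a gene, which this interval ignores. Adjacency rests on the gene names under which even probes of 1 gene correlated at 0.111, so this value excludes nothing, although it meets the bound set for it beforehand.

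The 784 probes with a value on the flip array alone were outside the test. Of them, 23.3% were at least 2-fold on that array, against 23.2% of the shared probes, and their median was 0.12 against -0.02. They included an hsp70 probe at -5.07 and a glnA probe at 2.37, each without a value on the flop array.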
